A study of Mus musculus with 5 samples.

How the data were processed

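RNA was measured in hair follicle stem cells of mouse back skin collected at postnatal day 75. Both groups had received 1% RU-486 on the skin daily for 10 days from day 50, and skin was taken 15 days after that treatment ended. Per the labels' protocols, epidermal cells were released with trypsin and sorted as EpCAM-positive, Sca1-negative, α6-integrin-high and CD34-positive cells. RNA of 50000 sorted cells was purified, samples with an RNA integrity number above 8 were kept, and 50 ng of RNA went into polyadenylate-selected libraries for an Illumina HiSeq instrument. The genotype labels put 2 samples in Control (no Cre) and 3 in PRC1 i2KO (with K15-CrePR1). The control called replicate 3 here carries that number in its title and another in its description.

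The authors deposited a table of 55357 Ensembl genes with a gene type and a gene symbol, of which 1362 have no symbol and 32433 have no read. Per the file headers, each library has a column of counts, whose fractional values show that they are expected counts (9.06% of genes have at least 1 fractional value). The authors also deposited a TPM column for each library, which is scaled to gene length and to a fixed total and so keeps no depth. The submitters' processing notes name STAR 2.7.9a, RSEM 1.3.3, DESeq2 1.38.2 and the build mm39, without saying which step each served; strandedness and the gene annotation are not given in the sources used here. The genome supplied for this work was of another build, so no coordinates are given and gene names are those of the deposited table. Counting by expectation shares reads between near-identical genes, so values of close paralogs, of overlapping genes and of antisense pairs are uncertain. No library pair agreed within sampling noise (chi-square per degree of freedom from 9.93 to 41.3 within groups), so no libraries were merged.

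Expected counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr on the groups, libraries were scaled with TMM factors (0.983 to 1.02), and a quasi-likelihood F test with robust dispersions was fitted on all 5 libraries with genotype as the only term. P-values were adjusted by Benjamini-Hochberg over 15665 genes, and genes with an adjusted p under 0.05 were called. CPM values use the same scaling, the SE of a log2 fold change is its size divided by the square root of the F statistic, and n is 2 for Control and 3 for PRC1 i2KO. A fold against a group with 0 reads is a lower bound against a floor of 3 reads summed over that group, equal to 0.0745 CPM in Control and 0.0601 CPM in PRC1 i2KO. With 1 to 3 reads in a group, the ratio of summed reads is given with an exact 95% binomial interval. Such intervals and floors cover counting error only, since no molecular identifiers are named in the sources used here.

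In all 32 gene lists (17 of pathways and states, 15 of cell types, the sort gate and sex-linked genes) were fixed before the data were examined, as were the tests, the rule for named genes and all but the last 2 of the alternatives named below. Of these, 27 had at least 5 tested genes and were tested with camera in limma 3.58.1 (preset correlation 0.01, log2 CPM with a prior count of 2), 3 had fewer, and the sort gate and sex-linked genes were read per library. Adjusted p-values of lists run over these 27. The calls were also made with a correlation estimated for each list, and with fry, which tests whether a list's genes move, on balance, in 1 direction. A call lost with an estimated correlation does not by itself show that correlated genes had made it, as set out below. The rule for named genes took Ring1 and Rnf2 and 16 genes of bulge identity, cycling, signalling and the sort gate whatever their result. It further took the 12 largest fitted rises and the 12 largest falls among called genes with a mean of at least 1 CPM, non-overlapping libraries and a symbol that is not a clone or predicted name. From each list it took up to 4 called members with the smallest adjusted p, or the 2 with the highest level where none was called. The rule selected 135 genes, of which most are given in the text and 1 is not reported here; others are marked as named after their values were seen.

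The fit was tested on simulated counts of 15665 genes with the means and depths of these libraries and 200 changed genes. It recovered 13 of 67 genes changed 1.5-fold (19.4%), 42 of 67 changed 2-fold (62.7%) and 47 of 66 changed 4-fold (71.2%), with 5 false among 107 calls. In the real data 33.9% of genes were called, and the Benjamini-Hochberg cut-off depends on the share that changed. These recovered shares therefore do not carry over to the real comparison. With no change planted, camera called 0 of 27 lists, and it called the S phase list when its genes were raised 1.5-fold. The simulated genes varied independently of each other. Those 0 calls therefore do not bear on lists whose genes vary together, such as bulge genes (estimated correlation 0.533) and G2 and M phase genes (0.556). The alternatives were DESeq2 1.42.0, RLE factors, library totals alone, no filter and a stricter filter (at least 10 counts in 4 libraries), dispersions without the robust option, limma on log2 TPM with pseudocounts of 1 and 0.1 and with or without a minimum mean of 1 TPM, the replicate number as a block, leaving out each library, thinning to the shallowest library and keeping only the 3 deepest libraries; the last 2 were added after seeing the data.

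Mitochondrial genes took 2.12% to 2.95% of counts. Ribosomal protein genes took 3.25% and 3.18% in the controls and 4.86%, 4.88% and 4.87% in PRC1 i2KO. The first principal component of log2 CPM held 71.1% of the variance and separated the groups. Across genes, which are not independent replicates, log2 CPM correlated at 0.956 to 0.967 within groups and 0.857 to 0.900 between them. Figures were drawn with matplotlib 3.10.9.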

Results

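Hair follicle stem cells sit in the bulge of the follicle, where they stay quiescent between phases of hair growth. Transcripts of such cells, sorted from mouse back skin at postnatal day 75, were compared between 2 groups. PRC1 is the Polycomb complex whose catalytic subunits, Ring1a (gene Ring1) and Ring1b (gene Rnf2), place ubiquitin on histone H2A. The 2 Control libraries came from mice that lacked Ring1a and carried floxed Ring1b alleles. The 3 PRC1 i2KO libraries came from mice of that genotype that also carried K15-CrePR1, a Cre recombinase driven by a keratin 15 promoter and activated by RU-486. Because Ring1a was absent from both groups, the comparison asks what the loss of Ring1b together with the presence of Cre changes in these cells. Libraries are named by their group and the number in their title, so the controls are replicates 1 and 3. Controls held 8270419 and 32463173 estimated reads, and PRC1 i2KO replicates 1, 2 and 3 held 9675996, 21102727 and 18657555. The labels do not say that the libraries came from separate animals, so the p-values measure the spread between these samples, which may be technical.

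The targeted genes were read first. Rnf2 (ENSMUSG00000026484) stood at 67.9 and 57.7 CPM in Control replicates 1 and 3 and at 48.1, 46.6 and 50.2 CPM in PRC1 i2KO replicates 1, 2 and 3, a log2 fold change of -0.37 (SE 0.12, edgeR adjusted p = 0.0363). That call was lost without Control replicate 1 (adjusted p = 0.251) and without PRC1 i2KO replicate 1 (0.0993) or replicate 2 (0.118), and DESeq2 did not make it (0.0612). Ring1 (ENSMUSG00000024325) stood at 28.9 ± 1.95 CPM in Control (SD, n = 2) and 24.3 ± 4.54 CPM in PRC1 i2KO (SD, n = 3; edgeR adjusted p = 0.36). A deleted exon leaves the reads of the rest of a transcript in place, so gene-level reads do not check the genotype of either gene.

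The PRC1 i2KO libraries had lower levels of bulge stem cell transcripts than the controls. Their levels of transcripts of the upper follicle, the sebaceous gland and differentiating epidermis were higher, and those of genes of S, G2 and M phase were higher too. Cd34, the surface marker by which the cells were sorted, fell 79.3-fold (log2 fold change -6.31, and -7.11 without PRC1 i2KO replicate 3), while Krt79, a keratin of the upper follicle, rose 65.0-fold and Mki67, a marker of cycling cells, rose 18.4-fold. Of 26 Hox genes 21 fell, and of 132 transcription factors of other lineages 13 had enough reads to test, of which 3 rose and 3 fell.

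In all, 5310 of 15665 tested genes (33.9%) passed edgeR's quasi-likelihood test at an adjusted p under 0.05, of which 2939 rose and 2371 fell in PRC1 i2KO. At least 2-fold changes were found in 2712 genes, 1695 higher and 1017 lower. In 5306 of the 5310 genes, every PRC1 i2KO library lay on the same side of both controls, as did 9314 of all tested genes (59.5%, against 20% by chance for groups of 2 and 3). This held for each called gene that the rule for named genes selected (126 of 126). That rule itself required non-overlapping libraries of the largest rises and falls, so for those genes the outcome was fixed by selection. The count of named genes is therefore no separate evidence beside that of all called genes. Leaving out PRC1 i2KO replicate 1, 2 or 3 gave 4101, 3778 and 5856 calls, of which 4013, 3734 and 4988 were among the 5310. Fits that kept a single control called fewer genes than the fit on all 5 libraries. On the deposited TPM, 1725 genes rose and 2106 fell (limma, log2(TPM + 1)), so that the share that rose was 45% in place of 55.3%; that scale moved the median gene by -0.147 on the log2 scale. Ribosomal protein genes took 3.25% and 3.18% of counts in the controls and 4.86%, 4.88% and 4.87% in PRC1 i2KO.

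**Figure D1:**
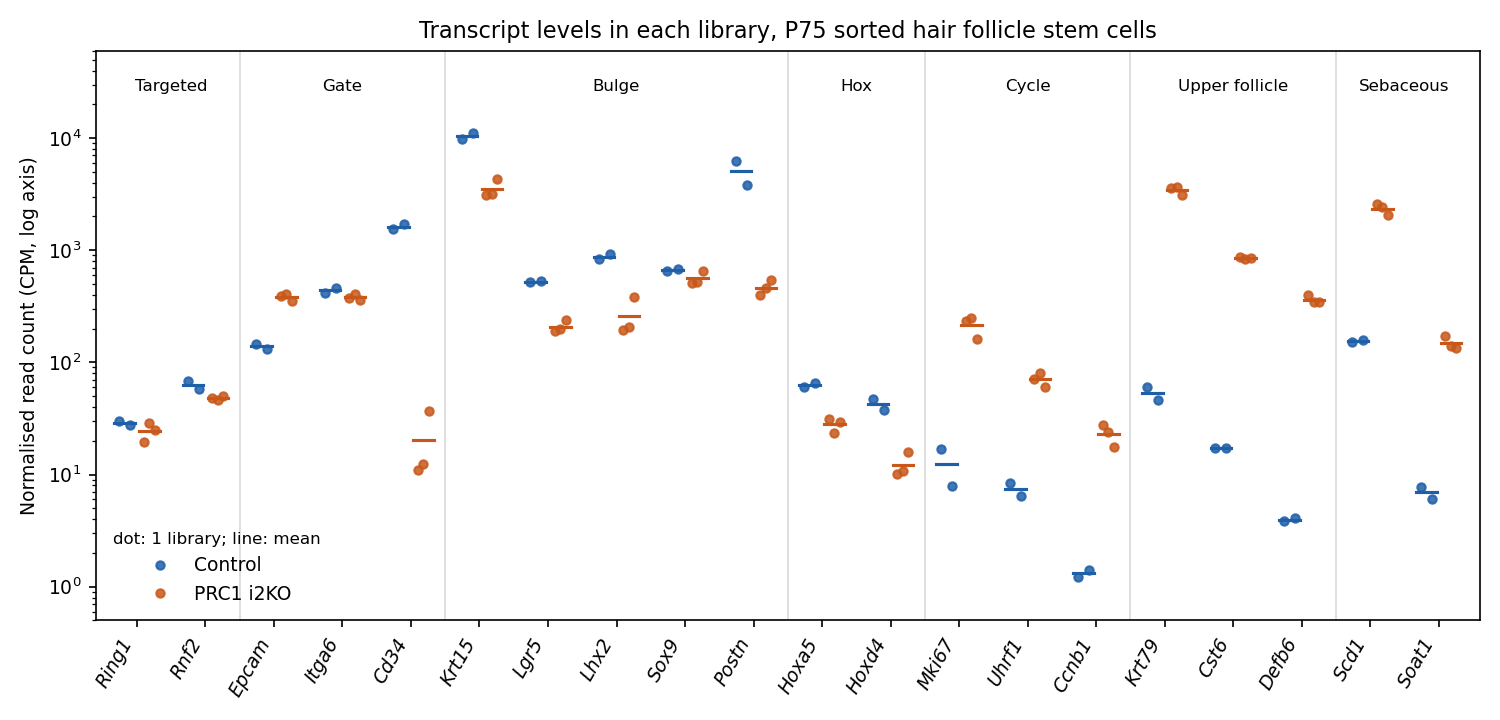
Normalised read counts (CPM, log axis) of 20 genes in each of the 5 libraries, where a dot is 1 library and a short line the mean of its group (Control, n = 2; PRC1 i2KO, n = 3). Cd34 lies at 1548 CPM or higher in both controls and at 37.2 CPM or lower in all PRC1 i2KO libraries, Krt79 lies at 59.8 CPM or lower in the controls and at 3087 CPM or higher in PRC1 i2KO, and Sox9 did not pass the test.

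Of 30 bulge stem cell genes, 23 fell, none rose and 7 did not pass the test (24 fell when adjusted over the list alone), while 1 rose and 17 fell without Control replicate 1. Cd34 (ENSMUSG00000016494) stood at 1623 ± 105 CPM in Control (SD, n = 2) and 20.2 ± 14.8 CPM in PRC1 i2KO (SD, n = 3; edgeR adjusted p = 0.00653). The adjusted p of Cd34 was 0.0567 without Control replicate 1 and 0.0528 without Control replicate 3, and its log2 fold change of -6.31 lay between -6.03 and -7.11 with any 1 library left out, the largest without PRC1 i2KO replicate 3. Krt15, a keratin of bulge and basal cells, fell 3.0-fold from 10513 CPM, and Lgr5, a receptor that marks follicle stem cells, fell 2.50-fold from 522 CPM. Igfbp5, Ltbp2 and Postn, which encode secreted proteins, each fell 10.1-fold to 10.9-fold. Krt24 fell 80.7-fold from 703 CPM (log2 fold change -6.34, and -7.14 without PRC1 i2KO replicate 3). Lhx2, a transcription factor of bulge cells, fell 3.38-fold, and Fgf18, a growth factor of resting follicles, fell 40.9-fold, calls that were lost without Control replicate 3 (adjusted p = 0.0803 and 0.063), for Lhx2 also without Control replicate 1 (0.0689). The size of the fall of Fgf18 (log2 fold change -5.36) hung on single libraries, at -4.46 without Control replicate 3 and -7.33 without PRC1 i2KO replicate 3. Nfatc1, a transcription factor of quiescent bulge cells, was at the threshold (log2 fold change -0.82, edgeR adjusted p = 0.0496) and was not called without Control replicate 1 (0.213), Control replicate 3 (0.157), PRC1 i2KO replicate 1 (0.0779) or PRC1 i2KO replicate 2 (0.0937). Sox9, Foxc1 and Bmp6 did not pass, at log2 fold changes of -0.24, 0.18 and 0.36, though without PRC1 i2KO replicate 3 Sox9 was called (-0.36, edgeR adjusted p = 0.00604) and Bmp6 turned to -0.13. The list as a whole was lower by camera (adjusted p = 1.01e-11), but not with an estimated correlation (adjusted p = 0.315 with an estimated correlation).

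The other genes of the sort gate were read in each library. Epcam, used as a positive marker, rose 2.77-fold, from 138.5 ± 9.69 CPM (SD, n = 2) to 383.5 ± 25.7 CPM (SD, n = 3; edgeR adjusted p = 1.2e-05). Itga6, the α6-integrin gene, stood at 439 and 382 CPM (edgeR adjusted p = 0.186). Ly6a, which encodes the negative marker Sca1, stood between 0 and 2.28 CPM in all 5 libraries (edgeR adjusted p = 0.108, and 0.0489 without Control replicate 3).

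Markers of neighbouring epithelial cells were higher alongside the lower bulge genes. Of 10 markers of basal interfollicular epidermis and infundibulum, 7 rose and 3 did not pass (7 rose when adjusted over the list alone). Krt79 (ENSMUSG00000061397) went from 53.2 ± 9.37 CPM (SD, n = 2) to 3440 ± 306 CPM (SD, n = 3; edgeR adjusted p = 8.41e-08). Cst6, a cysteine protease inhibitor, rose 49.6-fold, Defb6, a defensin, rose 89.8-fold, and Ly6d rose 48.8-fold. All 14 sebaceous gland markers rose, also when adjusted over the list alone. Among them Scd1, a fatty acid desaturase, went from 155.5 ± 2.97 CPM (SD, n = 2) to 2337 ± 267 CPM (SD, n = 3), Soat1, which esterifies cholesterol, rose 22.1-fold, and the lipid enzymes Elovl3 and Far2 rose 41.7-fold and 11.3-fold. Of 20 suprabasal epidermis markers, 17 rose and 1 fell, over all genes and over the list alone. Ivl, a cornified envelope protein, rose 13.9-fold, Grhl1, a regulator of keratinocyte differentiation, rose 4.34-fold, and Dsg1a and Krt77 rose 3.96-fold and 4.23-fold. The member that fell was Calml3 (2.33-fold lower), named after its values were seen; on unfiltered TPM 11 of these markers rose. By camera these 3 lists were higher (adjusted p = 1.43e-07, 6.73e-12 and 5.04e-08), and none was called with an estimated correlation (adjusted p = 0.288 for each with an estimated correlation).

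Cell cycle genes were also higher. All 30 G2 and M phase genes rose, also when adjusted over the list alone, with a median log2 fold change of 3.74. Kif20a and Cdc20, which act in mitosis, rose 19.9-fold and 10.9-fold, and Ccnb1, the mitotic cyclin B1, rose 17.0-fold from 1.32 ± 0.12 CPM (SD, n = 2) to 23.1 ± 5.0 CPM (SD, n = 3). Of 28 S phase genes, 24 rose and 4 did not pass (25 rose when adjusted over the list alone). Uhrf1, which maintains DNA methylation, rose 9.77-fold, Clspn, a replication checkpoint gene, rose 33.3-fold (log2 fold change 5.06, and 4.43 without Control replicate 3), and the replication helicase genes Mcm2 and Mcm5 rose 4.61-fold and 6.72-fold. Mki67 went from 12.4 ± 6.29 CPM to 215 ± 47.9 CPM (edgeR adjusted p = 0.00194). By camera both lists were higher (adjusted p = 9.01e-19 and 1.02e-11), which an estimated correlation did not keep (adjusted p = 0.299 and 0.315 with an estimated correlation). On unfiltered TPM, 11 S phase genes rose in place of 24.

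Inhibitors of cyclin-dependent kinases went both ways. Of 6 tested, Cdkn2c, Cdkn2d and Cdkn2b rose 5.63-fold, 1.70-fold and 2.67-fold, Cdkn1b fell 1.24-fold, and 2 did not pass (3 rose and 2 fell when adjusted over the list alone; camera adjusted p = 0.707). Without Control replicate 1, without Control replicate 3 or without PRC1 i2KO replicate 2, 1 of the 3 rises was left (for Cdkn2d adjusted p = 0.0576, 0.116 and 0.0754, and for Cdkn2b 0.0561, 0.147 and 0.0752); that of Cdkn2b was also lost without PRC1 i2KO replicate 1 (0.0625), and 2 fell without PRC1 i2KO replicate 3. The call of Cdkn1b was lost without either control or without PRC1 i2KO replicate 1 or 2 (adjusted p from 0.0908 to 0.249). Cdkn2a, a locus long known as a Polycomb target, had 0 reads in both controls and 1 read over the 3 PRC1 i2KO libraries, and was not tested.

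Hox genes, the classical Polycomb targets, were lower in PRC1 i2KO. Of 26 tested, 21 fell, none rose and 5 did not pass (22 fell when adjusted over the list alone). Hoxd4 fell 3.42-fold, Hoxa5 fell 2.25-fold from 63.2 ± 3.56 CPM (SD, n = 2) to 28.2 ± 4.13 CPM (SD, n = 3), and Hoxb6 and Hoxb9 fell 2.41-fold and 2.49-fold. The list was lower by camera (adjusted p = 1.43e-07), though not with an estimated correlation (adjusted p = 0.347 with an estimated correlation). The count that fell was 11 without Control replicate 3, 13 without PRC1 i2KO replicate 2 10 in the 3 deepest libraries and 12 on unfiltered TPM.

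Of 132 developmental transcription factors of other lineages, 13 had enough reads to test. Among these 13, 3 rose, 3 fell and 7 did not pass (3 rose and 4 fell when adjusted over the list alone), with a median log2 fold change of -0.17 and a mean of 0.04, and the list was not called (camera adjusted p = 0.497). Irx4 rose 1.56-fold and Otx1 rose 6.83-fold to 1.90 CPM, while Dlx5 fell 3.90-fold and Irx3 fell 1.42-fold; Pax3 (rose) and Lmx1b (fell) are named after their values were seen. The call of Otx1 was lost without Control replicate 3 (adjusted p = 0.134), that of Irx3 without Control replicate 1 (0.0634), and those of Pax3 and Lmx1b whichever control was left out. In all, 1 gene of the list rose without Control replicate 3, 1 fell without Control replicate 1, and on the deposited TPM none rose. Of the untested genes, 81 had 0 reads in all 5 libraries. Summed over all untested genes, the level was 1.35 and 3.36 CPM in the controls and 3.32, 3.43 and 4.32 CPM in PRC1 i2KO.

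Most Polycomb group and H2AK119 deubiquitinase genes did not pass the test. Of 39 tested, 3 rose, 10 fell and 26 did not pass, over all genes and over the list alone (camera adjusted p = 0.231). Phf1, an accessory subunit of PRC2, fell 2.29-fold, Ezh1, a methyltransferase of PRC2, fell 1.64-fold (not called without Control replicate 3, adjusted p = 0.051), and Phc3 and Auts2 fell 1.57-fold and 1.59-fold. The rises, named after their values were seen, were Ezh2 (1.61-fold), Kdm2b (1.34-fold) and Bcor (1.28-fold). The number that fell was 5 without Control replicate 3, 6 without PRC1 i2KO replicate 1, 6 without PRC1 i2KO replicate 2 and 4 in the 3 deepest libraries; that which rose was 1 without Control replicate 1 and on TPM and 5 without PRC1 i2KO replicate 3.

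Genes of the BMP pathway, which holds bulge cells quiescent, fell more often than they rose. Of 19 tested, 8 fell, 1 rose and 10 did not pass (9 fell and 2 rose when adjusted over the list alone; camera adjusted p = 0.00436, and 0.433 with an estimated correlation). Id2, a transcriptional target of BMP, fell 4.69-fold, and Smad9, a transducer, fell 6.37-fold. Grem1, which encodes a secreted BMP antagonist, fell 9.38-fold from 791.5 ± 22.1 CPM (SD, n = 2) to 84.2 ± 24.4 CPM (SD, n = 3). The ligand gene Bmp7 rose 6.66-fold. Without Control replicate 1, 5 genes fell and 2 rose.

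WNT target genes and genes of the activated hair germ were mostly higher. Of 14 WNT targets tested, 8 rose, 1 fell and 5 did not pass (9 rose and 2 fell when adjusted over the list alone). Apcdd1, an inhibitor of WNT signalling, rose 10.5-fold, Lef1, a transcription factor of the pathway, rose 6.89-fold from 7.93 ± 2.02 CPM (SD, n = 2) to 52.6 ± 13.7 CPM (SD, n = 3), and Sox4 rose 4.65-fold. The member that fell was Lgr5, and Axin2 was just outside the threshold (log2 fold change 0.40, edgeR adjusted p = 0.0519, and 0.0424 when scaled by library totals). On the deposited TPM, 5 of these genes rose, and without PRC1 i2KO replicate 3, 2 fell. Of 18 hair germ genes, 10 rose, 3 fell and 5 did not pass (11 rose when adjusted over the list alone). Wnt10a rose 1.81-fold, while Msx1 fell 4.30-fold; Bmp2 and Hoxc13, the other members that fell, are named after their values were seen. Without Control replicate 3, 6 hair germ genes rose; 1 fell without Control replicate 1 or without PRC1 i2KO replicate 1, and 5 fell without PRC1 i2KO replicate 3. Both lists were higher by camera (adjusted p = 0.00188 and 0.0084), but with an estimated correlation neither was (adjusted p = 0.288 and 0.315 with an estimated correlation), and the hair germ list was not called under a stricter filter on low counts (adjusted p = 0.107).

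Hedgehog pathway genes went both ways, 3 of 11 up and 4 down (4 up and 4 down when adjusted over the list alone), and the list was not called (camera adjusted p = 0.56, downward, as its median of -0.39 but unlike its mean of 0.58). Ptch1, a receptor and target of the pathway, rose 1.79-fold from 103 ± 9.91 CPM (SD, n = 2) to 184 ± 14.4 CPM (SD, n = 3), a call that was lost on the deposited TPM (limma adjusted p = 0.0556). Cdon and Gas1, which encode co-receptors, fell 5.76-fold and 2.57-fold. Gli1 did not pass (log2 fold change 0.72, edgeR adjusted p = 0.0697), though it was called without Control replicate 1 (0.00143) and by DESeq2 (0.00646). On the deposited TPM, 1 gene rose.

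Genes that anchor basal cells to the basement membrane were lower. Of 18 hemidesmosome and basement membrane genes, 12 fell, 1 rose and 5 did not pass, over all genes and over the list alone (camera adjusted p = 3.86e-06, and 0.299 with an estimated correlation). Col7a1, the collagen of anchoring fibrils, fell 2.98-fold, Dst, a hemidesmosome plakin, fell 2.43-fold, and Lamb3, a laminin chain, fell 2.52-fold. Nid1, a basement membrane glycoprotein, rose 14.3-fold from 0.65 CPM.

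Wound and stress keratinocyte genes were mostly higher, 8 of 13 up and 2 down, over all genes and over the list alone (camera adjusted p = 0.00817, and 0.293 with an estimated correlation). The EGF receptor ligand gene Areg rose 27.4-fold (log2 fold change 4.78, and 5.69 without Control replicate 3), Sprr1a, a cornified envelope gene, rose 26.9-fold, and Krt16 rose 4.79-fold. Krt6a fell 7.42-fold from 772 CPM; it and Krt6b, which also fell and is named after its values were seen, are near-identical paralogs whose reads the counting could split. Without PRC1 i2KO replicate 2, 5 genes rose. Interferon response genes were mostly higher, 17 of 22 up and 1 down (18 up when adjusted over the list alone; camera adjusted p = 2.17e-06, and 0.299 with an estimated correlation). Oasl2 rose 11.2-fold, Oas3 12.5-fold (log2 fold change 3.64, and 4.72 without Control replicate 3) and Irf9, a transcription factor of the pathway, 2.15-fold. Mx1 had 0 reads in the controls and was at least 29.9-fold higher, against a floor of 3 reads over the group. Usp18, a negative regulator of the response, was the member that fell (3.12-fold lower), named after its values were seen and not called without Control replicate 1 or 3 or PRC1 i2KO replicate 1 or 2. Without Control replicate 3, 11 of these genes rose, with the stricter filter 11, and on the deposited TPM 9.

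Lists of early response, p53 and Merkel cell genes were not called. Of 21 immediate early and dissociation genes, Socs3, Egr2 and Ier2 rose and 18 did not pass (1 rose when adjusted over the list alone; camera adjusted p = 0.231). That count was 7 without Control replicate 1 and 1 without any other library, where 2 fell without Control replicate 3; the list was called without Control replicate 1 (camera adjusted p = 0.00106), without PRC1 i2KO replicate 3 (0.0363) and in the 3 deepest libraries (0.00898). Leaving out Control replicate 3 or any 1 PRC1 i2KO library ended the calls of Egr2 (adjusted p from 0.0514 to 0.0977) and Ier2 (0.0591 to 0.224). Of 20 p53 targets, Eda2r rose, Trp53inp1 and Sesn1 fell and 17 did not pass (1 rose and 1 fell when adjusted over the list alone; camera adjusted p = 0.711). Without Control replicate 1, 3 p53 targets rose and 1 fell, and 1 fell without PRC1 i2KO replicate 1 or 2; the call of Sesn1 was lost whichever library was left out (adjusted p from 0.0625 to 0.211). Of 5 Merkel cell genes tested, Krt18 had 0 reads in the controls and was at least 23.1-fold higher, Cck fell and 3 did not pass, over all genes and over the list alone (camera adjusted p = 0.711).

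Markers of cells outside the epithelium were read as well. Markers of 1 cell type stood at unlike levels in the controls, so a change in 1 marker need not reflect those cells. Among fibroblast markers, Col6a1 stood at 647 CPM and Pdgfra at 5.32 CPM. For melanocyte markers, Mitf stood at 157 CPM and Dct at 1.80 CPM. Of 10 immune markers tested, Cd74, H2-Ab1 and H2-Aa, genes of antigen presentation, rose 3.94-fold, 2.94-fold and 2.89-fold, and 7 did not pass (camera adjusted p = 0.231), though the list was called on the deposited TPM. The leukocyte gene Ptprc, named after its values were seen, stood at 0.559 and 0.565 CPM. Of 9 fibroblast markers tested, 6 fell and 2 rose (camera adjusted p = 0.0084, and 0.315 with an estimated correlation), and the list was not called without Control replicate 1 or on the deposited TPM (adjusted p = 0.0564 for each). Col6a1, a collagen, fell 22.1-fold from 647 CPM, Col1a2 fell 2.32-fold, Crabp1 fell 8.66-fold and Pdgfra fell 7.26-fold; Thy1 and Dcn, which rose, are named after their values were seen, and 1 of them was called without PRC1 i2KO replicate 1 or 2 and neither without Control replicate 3. Of 6 endothelial markers, Flt1 rose (camera adjusted p = 0.352), and 2 rose without PRC1 i2KO replicate 3. Of 6 melanocyte markers, Dct, Kit and Sox10 rose 8.51-fold, 9.49-fold and 4.14-fold, and Mitf fell 3.88-fold from 157 CPM (camera adjusted p = 0.221); without Control replicate 3 the log2 fold change of Kit went from 3.25 to 4.34. Of 7 Schwann cell markers, Ngfr and Sox10 rose, with a median log2 fold change of -0.41, a mean of 0.16 and an upward camera adjusted p of 0.923. The call of Sox10 was lost without either control (adjusted p = 0.0703 and 0.185) or without PRC1 i2KO replicate 2 or 3 (0.0937 and 0.0923), and that of Ngfr without Control replicate 3 (0.0663). Over these lists alone, the counts were 3 immune markers up, 2 fibroblast markers up and 6 down, 1 endothelial marker up, 4 melanocyte markers up and 1 down, and 2 Schwann cell markers up.

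Of 8 tested markers of hair shaft and inner root sheath, 4 rose and 1 fell (camera adjusted p = 0.291). Ctsc rose 17.0-fold (log2 fold change 4.09, and 3.36 without Control replicate 3), Tchh 1.71-fold and Krt32 2.91-fold, and Krt75 fell 5.38-fold. The call of Krt32 was lost without Control replicate 3 (adjusted p = 0.0856), where 2 markers rose. Of 6 companion layer and inner bulge markers, Timp3 and Krt16 rose, Krt6a, Krt75 and Fgf18 fell and 1 did not pass (camera adjusted p = 0.831). Counts adjusted over each of these lists alone were the same. Muscle, adipocyte and erythrocyte markers had 3, 3 and 2 tested genes, too few for a list test. Tagln rose to 2.65 CPM. Lpl, a lipase, rose 52.2-fold from 1.53 CPM, Cidec, with 0 control reads, was at least 10.5-fold higher, and Lipe fell 2.31-fold. Hba-a1 had 0 and 35 reads and was at least 9.41-fold higher, and Hba-a2 had 46 and 1 reads, a ratio of 57.0 (95% counting interval 9.73 to 2300), but these are near-identical paralogs whose reads the counting could split. The calls of Tagln, Cidec, Hba-a1 and Hba-a2 were lost without Control replicate 1 (adjusted p = 0.0824, 0.0561, 0.0696 and 0.0554), those of the first 3 also without Control replicate 3 (0.0901, 0.137 and 0.16) and that of Tagln without PRC1 i2KO replicate 2 (0.0842). Over these lists alone the same 1 muscle, 3 adipocyte and 2 erythrocyte genes passed.

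**Figure D2:**
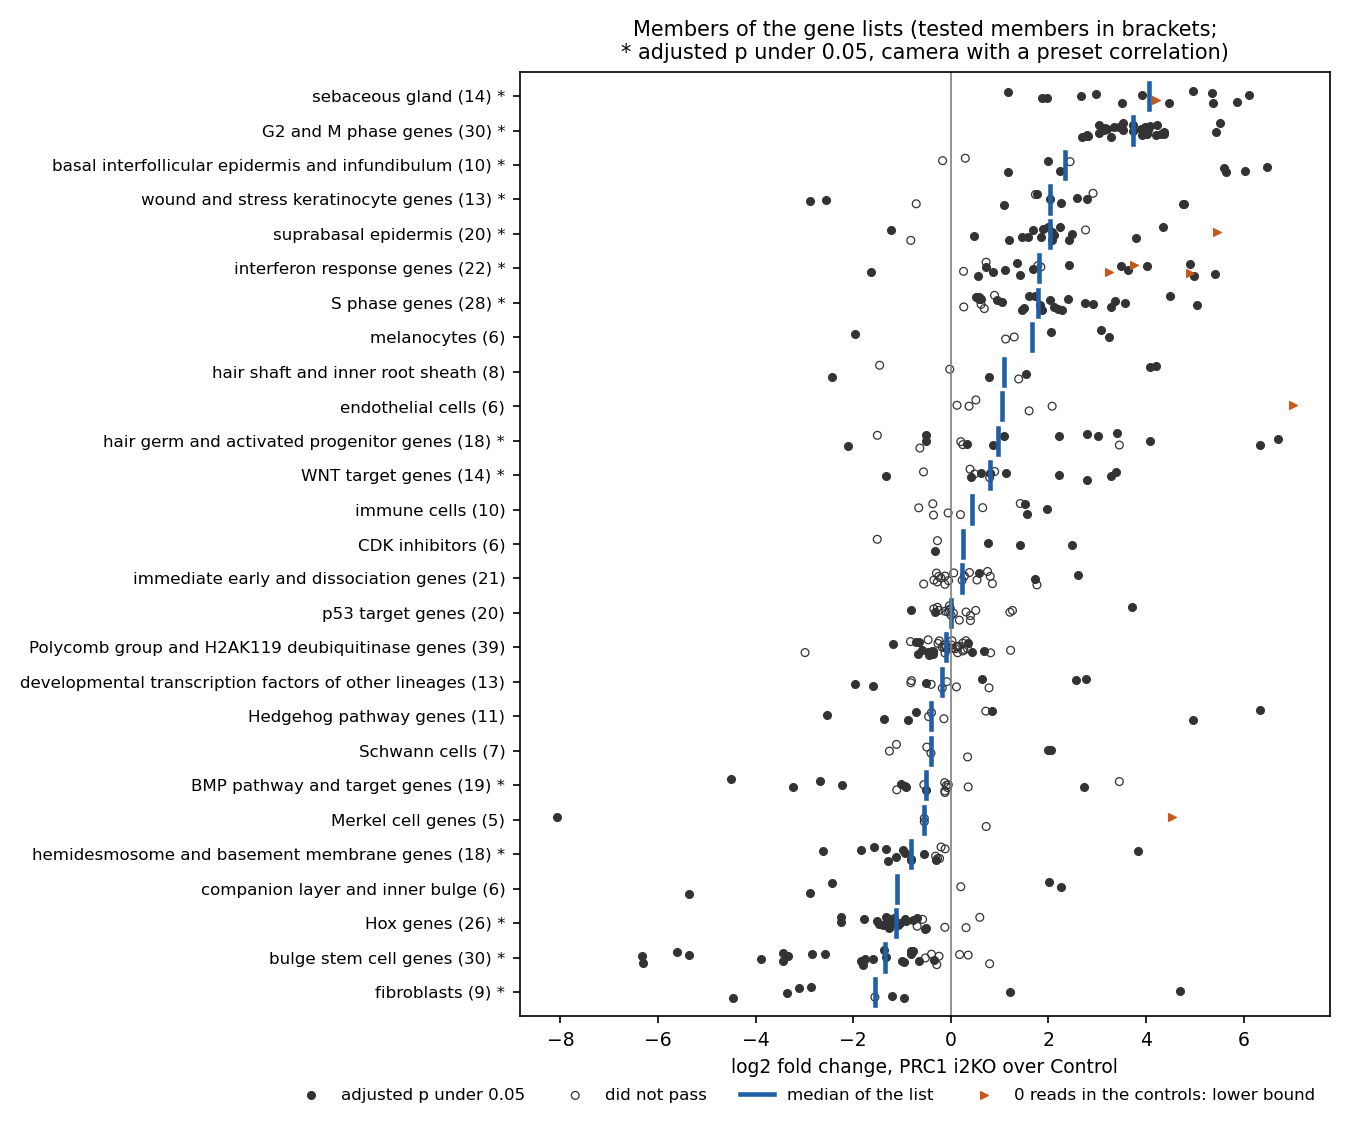
Fitted log2 fold change (PRC1 i2KO over Control, horizontal axis) of each tested member of the 27 gene lists with at least 5 tested genes, where filled dots passed an edgeR adjusted p of 0.05, open dots did not, triangles are lower bounds for genes with 0 reads in the controls and blue bars are medians. The 14 lists with an asterisk were called by camera with a preset correlation, 9 upward and 5 downward, and none of them with an estimated correlation.

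Among the 12 largest fitted rises, all had 0 reads in both controls, so their folds are lower bounds against a floor of 3 reads over the group. They were ranked by fitted fold, which exceeds the bound (for Dclk3 840 against 74.2). The bounds do not show that these 12 rose the most. Those of Sgo1, Hsd17b13, Tmc3 and Dclk3 lie under the 89.8-fold rise of Defb6. Ppp2r2c, a regulatory subunit of protein phosphatase PP2A, was at least 290.5-fold higher at 22.1 ± 11.4 CPM (SD, n = 3; edgeR adjusted p = 0.00528). Dchs2, a large cadherin, was at least 214-fold higher at 15.9 ± 2.51 CPM (SD, n = 3; edgeR adjusted p = 7.68e-06). The sodium channel subunit gene Scn2b, the VEGF receptor gene Flt1, Chil1 and Mtcl1 were at least 144-fold, 129-fold, 123-fold and 116-fold higher. Ndc80 and Sgo1, which act at the kinetochore and centromere in mitosis, were at least 95.5-fold and 67.5-fold higher. Acox2, an enzyme of peroxisomal oxidation, Hsd17b13, a lipid droplet protein, Dclk3 and Tmc3 were at least 97.6-fold, 73.4-fold, 74.2-fold and 74.0-fold higher.

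Among the 12 largest falls, Cck, which encodes cholecystokinin, had 668 reads in the controls and 3 in PRC1 i2KO, a ratio of 276 (95% counting interval 94.0 to 1341). Unc5c, a netrin receptor gene, had 228 and 1 reads, a ratio of 283 (50.2 to 11210), C1ql3 had 424 and 3 reads, a ratio of 175 (59.5 to 853), and C1rl had 135 and 2 reads, a ratio of 83.7 (22.7 to 698). Galnt15, a glycosyltransferase gene, fell 96.4-fold from 63.2 ± 20.1 CPM (SD, n = 2) to 0.59 ± 0.811 CPM (SD, n = 3; edgeR adjusted p = 0.00316), a fold set largely by PRC1 i2KO replicate 3 (log2 fold change -6.59, and -8.87 without that library). S100a4, a calcium-binding protein gene, fell 56.9-fold from 406 ± 47.4 CPM (SD, n = 2), and Sphkap, Ppp1r3c, Sncg and Slc14a1 fell 87.2-fold, 71.1-fold, 58.5-fold and 53.8-fold. Without PRC1 i2KO replicate 3 the log2 fold change of S100a4 went from -5.83 to -6.54, that of Sphkap from -6.45 to -7.27 and that of Sncg from -5.87 to -6.98, and that of Slc14a1 went from -5.75 to -7.03 without PRC1 i2KO replicate 1. Krt24 and Cd34 were also among these 12.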

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

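Thinning and the 3 deepest libraries were settings chosen after the data were seen. No gene called both in the original fit and under another setting changed sign. Of the 126 called named genes, 96 kept their call and direction under every setting that tested them. A setting that gave a gene no adjusted p was not counted against it. DESeq2 called 5388 genes (5118 shared), library totals alone 5264 and no filter 5875. On log2(TPM + 1) 1725 genes rose, on log2(TPM + 0.1) 1726, and without a filter on TPM 2996 were called and 1393 rose; the cause was not tested. Leaving out 1 library gave 3322 to 5856 calls, 2041 to 2960 of at least 2-fold, 1963 to 3099 that rose and 1359 to 2757 that fell, the lowest each time without Control replicate 3; where a control was left out, the lone control was assumed to vary like the other group. Thinning to the shallowest library called 5092 genes (4839 shared) and the 3 deepest libraries 2745, of which 1736 rose and 1009 fell with fewer samples. With an estimated correlation 0 of 27 lists passed, and with fry 17 did (CDK inhibitors, immune cells and melanocytes added). WNT target and wound lists had estimated correlations of -0.0232 and -0.0463, under the preset 0.01. Both still lost their calls (camera adjusted p = 0.288 and 0.293). A lost call under that setting therefore does not show that correlation between genes was the reason. Leaving out PRC1 i2KO replicate 1 or 2 gave 14 lists, and leaving out replicate 3 gave 15.

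Directions of uncalled lists turned, at these adjusted p-values: Merkel cell without a filter (0.973), companion layer with the stricter filter (0.727) and fry (0.138), p53 targets on TPM (0.976) and without Control replicate 3 (0.879; 0.284 without Control replicate 1), Schwann cell with the title-number block (0.851), and immediate early genes without Control replicate 3 (0.554; called at 0.00106 without Control replicate 1). Bmp6, uncalled, turned to -0.128 with the description-number block and -0.127 without PRC1 i2KO replicate 3, against 0.568 without PRC1 i2KO replicate 1; the cause was not tested. Only 2 title numbers are shared, with correlations of deviations of 0.0737 and 0.115. With 2 controls the deviations mirror each other, so these values do not settle whether the replicate number pairs the samples. The 2 libraries numbered 1 also share traits given in the last paragraph. A block on title numbers gave 4421 calls (4213 shared) and 14 lists, and one on description numbers 5314 and 15 (immediate early genes added). Depth limits genes at few reads: the floor of 3 reads is 0.369 CPM in Control replicate 1 and 0.0933 CPM in Control replicate 3.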

Other observations

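All tests below were chosen after the results were seen, except that of gene families, which was written before families were counted. Genes were grouped into 158 families by the letters that open their symbols, and each family with at least 10 tested protein-coding genes was tested for an excess of rises or of falls among 13301 genes (1-sided exact Fisher test, 316 tests, Benjamini-Hochberg adjusted). In all, 8 tests passed. The Fisher test counts genes as independent units, though genes of a family can move together in the same 5 libraries. Nor does it match a family to genes of like abundance, for which small changes are equally easy to call. Its p-values therefore do not measure the spread between samples. Genes of the large ribosomal subunit rose together, 42 of 49 in the Rpl family (adjusted p = 1.38e-19), with a small median change of 0.56 on the log2 scale; Rpl13a went from 502 ± 20.1 to 857 ± 24.7 CPM. In the Rps family 30 of 45 rose (adjusted p = 7.32e-09); it holds 10 kinase genes, of which 2 fell (Rps6ka2 and Rps6ka4), and the binding protein gene Rps19bp1, which rose, and of its other 34 members 29 rose. In the Eif family, named for translation initiation factors, 24 of 53 rose (Fisher adjusted p = 0.00273), with Eif5a 1.77-fold higher and Eif5a2 alone lower. That family is set by symbol and does not hold initiation factors alone. Its rises include the binding protein genes Eif4ebp1 (2.24-fold) and Eif4ebp2 (1.49-fold). Atp genes rose in 30 of 69 (Fisher adjusted p = 0.00106), among them the mitochondrial ATP synthase gene Atp5b, 2.06-fold higher. In the Atp family 7 genes fell, Atp2a3 the most (log2 fold change -2.49). On the deposited TPM, 29 Rpl, 24 Rps, 8 Eif and 20 Atp genes rose and each family's median stayed above 0; in the 3 deepest libraries these counts were 7, 9, 6 and 18.

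Proteasome subunit genes (Psmb) rose in 9 of 10 (adjusted p = 0.000496). The subunits of the immunoproteasome, Psmb8, Psmb9 and Psmb10, rose 9.98-fold, 5.66-fold and 3.97-fold, beside Psmb5 at 1.86-fold. The fold of Psmb8 is uncertain because its controls differed widely (8.45 ± 5.80 CPM, SD, n = 2, against 75.1 ± 1.15 CPM in PRC1 i2KO, SD, n = 3). Skint genes, a rodent family expressed in skin epithelium and tied to epidermal T cells, rose in 10 of 11 (adjusted p = 0.000152); Skint3 went from 5.84 ± 1.49 to 174 ± 68.9 CPM, though close paralogs of this family may share reads, which the 8 families past the threshold do not test. Frizzled genes, the WNT receptors, fell in 8 of 10 (adjusted p = 0.00106). Fzd2 fell 4.52-fold from 580 CPM, Fzd3 fell 3.53-fold from 208 CPM and Fzd9 fell 9.56-fold, while Fzd10 rose 3.89-fold. The Mcm family, which overlaps the S phase list, rose in 7 of 10 (adjusted p = 0.0458). Counts on the deposited TPM were 5 Psmb, 9 Skint and 4 Mcm genes up, 1 Mcm gene down, and 1 Fzd gene up and 7 down. Skint genes that rose numbered 7 without Control replicate 3, Psmb genes 5 in the 3 deepest libraries, where 5 Fzd genes fell.

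Cd34 was nearly absent, and other bulge transcripts were lower, in PRC1 i2KO libraries sorted on CD34 protein. Dilution of control-like bulge cells by cells without bulge transcripts would leave every bulge gene at the share that Cd34 kept, 0.677%, 0.759% and 2.29% of its control level in the 3 libraries, but the 30 bulge genes kept a median of 39.4%, with lower quartiles of 9.68%, 10.6% and 14.9%. That argues against dilution by cells without bulge transcripts as the whole cause. Dilution by cells that hold some of these transcripts could also leave unequal shares and was not tested. Another follicle population taken in by the gate could raise markers of the upper follicle and sebaceous gland. That gate selects for CD34 and against Sca1 and so should remove infundibulum and interfollicular cells. Ly6a, the gene of Sca1, stood between 0 and 2.28 CPM in all 5 libraries. Of 24 tested markers of the upper follicle and sebaceous gland, 21 rose. Among all 24 markers, only Ly6a stands in another list, that of the sort gate, and 16 were at 1 CPM or more in the controls. Their most abundant member, Krt79, reached 3440 CPM. Their level was alike in the 3 PRC1 i2KO libraries (highest over lowest 1.22), so a shift of gate and a change of state of bulge cells after loss of Ring1b, which was not tested apart from it, cannot be told apart, because both go with the genotype.

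Among 132 transcription factors of other lineages, many of them known Polycomb targets, all but 13 had too few reads to test. A rise too small to be seen at this depth stays open. The summed reads of the untested genes had a ratio of 1.27 between PRC1 i2KO and Control (95% counting interval 1 to 1.61), but the libraries overlapped, from 1.35 to 3.36 CPM in the controls and from 3.32 to 4.32 CPM in PRC1 i2KO. Ring1b kept by the sorted cells may also leave these genes low, and Rnf2 gene-level reads, which changed by -0.374 on the log2 scale, do not see a deleted exon. These explanations and low levels that do not need Ring1b cannot be told apart, because no value here decides between them.

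PRC1 i2KO replicate 3 lay closest to the controls, with correlations across genes of 0.90 and 0.895 to them against 0.857 to 0.878 for the other PRC1 i2KO libraries. If a share of control-like cells were the cause, all genes would give 1 share. Over 761 called genes that changed at least 2-fold and reached 50 CPM in either group, the implied share had a median of 13.4% and quartiles of 2.96% and 28.0%, against quartiles of -3.26% and 6.65% for replicate 2 set against replicate 1. Cd34 and Krt24 gave 1.59% and 1.57%, Col17a1 17.5%, Lhx2 26.5% and Mki67 35.6%, which argues against an admixture as the whole cause. A milder or later response in that sample stays open and was not tested.

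Xist stood at 20.6 and 31.6 CPM in Control replicate 1 and PRC1 i2KO replicate 1 and at 1.74, 0.376 and 0.526 CPM in Control replicate 3 and PRC1 i2KO replicates 2 and 3. The 2 libraries with more Xist share the title number 1, have the fewest reads and are the only ones above 0 on the second principal component (23.4 and 48.6). The Y-linked gene Ddx3y stood between 61.1 and 85.2 CPM in all 5 libraries. Of the other Y-linked genes, Kdm5d stood at 53.2 CPM in Control and 40.9 CPM in PRC1 i2KO (edgeR adjusted p = 0.0358), Uty at 31.3 and 28.6 CPM and Eif2s3y at 56.8 and 58.1 CPM. Pooling of male and female animals in a library could give both kinds of reads and would change what n counts. That possibility was not tested. Leaving out both libraries numbered 1 also leaves a single control, so the calls lost there do not bear on pooling. With 0 reads in both controls, 33 genes had a mean of at least 3 CPM in PRC1 i2KO, and 1 gene showed the opposite.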
